A study of Mus musculus with 59 samples.

How the data were processed

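Messenger RNA was measured in the cortex of C57/Bl6 mouse pups, 8 days old, on Illumina MouseRef-8 bead arrays. Per the labels' protocols, total RNA was extracted with the miRNeasy kit and biotinylated cRNA was made with a MessageAmp kit. The 59 arrays fall into 16 groups of treatment (sham, PC, HI and HIPC) and time (0, 3, 8 and 24 h), taken from the labels with their replicate number and BeadChip. The labels name 15 BeadChips. Of these, 4, 5, 4 and 3 hold the arrays of 0, 3, 8 and 24 h, with BeadChip 5 counted under both 8 and 24 h. The array labels of HI replicate 3 of 3 h and of sham replicate 1 of 24 h are doubtful, so each had a block of its own. For the former, the profile file of the striatum holds signal under the same array label. It correlated with the array's own signal at 0.965, and the other HI arrays of 3 h did so at 0.993 to 0.997. Within a time, array position and treatment cannot be told apart.

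The main values are the deposited non-normalized signal intensities of 25697 probes, and 837 deposited rows held no values. The sample probe profile of the 24 h arrays holds average signal intensity and detection scores from BeadStudio 3.4.0 without normalization, per the file headers. The deposited detection score lies between 0 and 1 and is high for detected probes. The deposited processed values are a ratio: within each time they follow the signal of each probe (r = 1.0 on the log2 scale), and the mean over the sham arrays of that time is 1, so each is a normalized signal divided by that mean. The normalization behind these ratios is stated in no header. Their medians per array ran from 0.913 to 1.05. In the profile files 128 columns of single arrays matched no sample of the series and were not used. Probes took their gene symbols from the accessions in the files (23876 probes), or from the target's symbol (728) or synonym (709), and 384 kept the name on the array.

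The plan was background correction with negative control probes (neqc). This was not possible with the values used here, so the normexp method of limma 3.58.1 (R 4.3.3) estimated the background from all probes of each array, with an offset of 16. Log2 values were then quantile normalized. The background threshold of 6.215 on this scale is the median over 15 arrays of 24 h (5.981 to 6.452) of the lowest value with a deposited detection score of at least 0.99, and 98.7% of calls on those arrays were the same. At 24 h, 9914 to 11697 probes per array had such a score, and the mean signal per array was 238.1 to 656.3 over all times. Probes above the threshold on at least 3 arrays were kept (12763 probes). Each gene was represented by its probe with the highest mean, which gave 9458 genes. Where the mean or every array of the dimmer group lay below the threshold, the fold is a lower bound, taken over the threshold itself.

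Groups were compared with limma's lmFit and eBayes on all 59 arrays with 1 mean per group, in 19 contrasts (prior degrees of freedom 5.32). Within each contrast p-values were adjusted by Benjamini-Hochberg, and genes under 0.05 are called. The 19 contrasts set HI, PC and HIPC against sham and HIPC against HI at each time, and the HI effect against that of the time before. Of 27 gene lists, 26 had at least 5 tested members; these were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. The lists cover immediate early genes, hypoxia-inducible factor targets, glycolysis, heat shock, unfolded protein response, oxidative stress, apoptosis, cytokines, interferon response, cholesterol synthesis, glucocorticoid-responsive genes, ribosomal proteins, respiratory chain, cell cycle and synapses. The others mark microglia, neutrophils, astrocytes and reactive astrocytes, oligodendrocytes, excitatory, inhibitory and striatal neurons, endothelium, choroid plexus and meninges; the erythroid list was too short. The samples, comparisons, lists, naming rule and alternatives below were fixed before the data were examined. Under alternatives the list tests used camera on ranked statistics, which with the main settings gave the same adjusted p-values as above.

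Genes were named by rule: for each comparison, the 10 largest rises and the 10 largest falls among called genes with a gene symbol and no overlap between the arrays of the 2 groups, up to 4 called members of each list with the largest differences, and all called genes where 5 or fewer passed. The text gives a part of these 471 gene differences, and some genes that the rule chose are not reported here. A named gene may be given in other comparisons too. HI and HIPC against PC at 24 h were added after the data were seen.

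The alternatives were no background correction, an offset of 50, median scaling, the authors' ratios, no filter (17877 genes), a stricter filter (8839 genes), every probe, only the arrays of the times compared, array weights, the BeadChip as a fixed or random block, the replicate number as a block, a log2 difference of at least 1, and each array left out in turn. The scripts were tested on simulated data with 9458 genes. In a simulated HI against sham at 0 h, 66%, 97% and 100% of genes changed by 0.5, 1 and 2 log2 units were recovered with 7 false calls, and at 24 h 68%, 94% and 100% with 8. No array repeated another, since the largest number of probes whose signal intensities in 2 arrays lay within 0.05 of each other was 177. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.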

Results

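Messenger RNA was measured in the cortex of mouse pups 8 days old. There were 4 treatments at 4 times after the hypoxia (0, 3, 8 and 24 h). Hypoxic ischemia (HI) means closure of the right common carotid artery followed by breathing 8% oxygen for 1 h, a model of the brain injury of newborns deprived of oxygen. Hypoxic preconditioning (PC) was done without closing the artery, and the HIPC group is labelled as having had both preconditioning and hypoxic ischemia. The sham group is the control, and the labels leave open whether its pups also breathed low oxygen. Each group held 4 arrays, except the HI and HIPC groups at 0 and 8 h and the sham group at 3 h, which held 3. By group the mean signal was 480.4 to 499.8 at 0 h and 267.3 to 289.0 at 8 h. In sham and HIPC it was 465.2 and 565.1 at 3 h, and 342.2 and 413.1 at 24 h. The number of arrays limits the precision of every difference given here. No label says that the arrays of a group come from separate animals, so the p-values measure the spread between these samples, which may be technical. The 9458 genes with signal above background on at least 3 arrays were tested with limma, and every adjusted p is a Benjamini-Hochberg value from that test, or for gene lists, given by the median log2 difference of their members, from limma's camera. The arrays of a time lay on 3 to 5 BeadChips (the glass slides that hold several arrays) and, apart from 1 array with a doubtful label, no BeadChip held arrays of more than 1 time, so differences are given within a time, also with the BeadChip as a block and within the BeadChips that held both groups.

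The first question was what hypoxic ischemia changed in the cortex against sham, from its end to 24 h later. At 0 h, Depp1, a target gene of the FoxO transcription factors, was at least 3.76-fold higher (adjusted p = 2.52e-09) in HI (n = 3) than in sham (n = 4). Dusp1, a phosphatase that switches off MAP kinases, was 2.33-fold higher (log2 difference 1.22 ± 0.19 SE, adjusted p = 0.00033). Fos, a subunit of the AP-1 transcription factor, was 5.56-fold higher (2.48 ± 0.48 log2, adjusted p = 0.00367), with sham signal above background on 3 of 4 arrays. Its mean log2 value was 9.15 ± 1.00 (SD, n = 3) in HI and 6.67 ± 0.77 (SD, n = 4) in sham. In all, 30 of the 9458 genes passed limma's test, 29 higher and 1 lower. Of the 22 immediate early genes, which neurons switch on within minutes of stimulation, 9 rose and 0 fell (15 rose adjusted over the list alone; median 0.94, adjusted p = 1.14e-32, and 0.000103 with an estimated correlation), Npas4 (at least 1.99-fold) and Junb (2.39-fold) among them. Of the 5 neutrophil genes tested (of 17 fixed) 1 rose, S100a8 (at least 2.98-fold), and 3 did so over the list alone (median 0.87, adjusted p = 4.47e-06, and 0.0101 with an estimated correlation). Of the 20 glucocorticoid-responsive genes 1 rose, Dusp1, and 9 did so over the list alone (median 0.33, adjusted p = 3.59e-10, and 0.0296 with an estimated correlation). None of the 16 cytokine and chemokine genes passed over all genes and 3 rose over the list alone (median 0.42, adjusted p = 2.34e-06, and 0.366 with an estimated correlation). The red cell genes Hba-a1, a haemoglobin chain (2.48-fold), Slc4a1, the red cell anion exchanger (at least 1.95-fold, sham above background on 1 of 4 arrays), and Alas2, an enzyme of haem synthesis (2.3-fold), were also higher (0.00111 to 0.00327 in adjusted p). The single gene that fell was Hes5, a Notch target of neural progenitors (-1.04 ± 0.20 log2, adjusted p = 0.00388).

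With the BeadChip as a block, 41 genes passed, the log2 difference of Fos was 2.73 and the median of the immediate early genes was 0.94. Within the 3 BeadChips that held both groups, Fos was higher by 2.28 to 3.64 log2 units and the immediate early genes by a median of 0.62 to 1.47. With that block all 10 genes given here passed, and their log2 differences moved by at most 0.25 and the list medians by at most 0.08. In each such BeadChip all 10 genes and 4 lists kept their sign. The genes given here and below are a part of the 471 gene differences chosen by the naming rule. Of those 471, 43 did not pass with the BeadChip as a block, so the given genes do not stand for all of them. Without HI replicate 3 the count was 6 genes, the cytokine median 0.27, and the calls of Fos (1.94 log2, adjusted p = 0.219), Junb (1.06 log2, 0.205), Alas2 (1.13 log2, 0.0707), Hes5 (-0.87 log2, 0.205), Npas4 (adjusted p = 0.179) and S100a8 (0.145) ended. Without HI replicate 1 it was 17 genes, and S100a8 (adjusted p = 0.0543), Slc4a1 (0.0543), Alas2 (1.05 log2, 0.0543) and Hes5 (-0.93 log2, 0.0738) did not pass. The sham and PC arrays of 0 h on BeadChip 11 stood apart, at -4.69 and -0.67 on the first principal component (68.1% of the variance) where the other arrays of 0 h lay at 27.06 to 41.14. Without both, 26 genes passed, 20 of the 30 among them.

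At 3 h, Fos was 20.9-fold higher (log2 difference 4.39 ± 0.48 SE, adjusted p = 1.7e-08), at a mean log2 value of 11.38 ± 0.21 (SD, n = 4) in HI and 7.0 ± 0.25 (SD, n = 3) in sham. Fosb, another AP-1 subunit, was at least 4.61-fold higher (adjusted p = 1.05e-10). Tnfrsf12a, the receptor of the cytokine TWEAK, was at least 2.91-fold higher (adjusted p = 9.18e-05), and Esm1, a proteoglycan secreted by activated endothelium, at least 2.23-fold higher (adjusted p = 9.18e-05). In all, 289 of the 9458 genes passed limma's test, 135 higher and 154 lower. Of the 22 immediate early genes 14 rose (17 over the list alone; median 0.88, adjusted p = 2.46e-25, and 0.000417 with an estimated correlation). Of the 16 cytokine, chemokine and endothelial activation genes 7 rose (11 over the list alone; median 0.78, adjusted p = 1.09e-13, and 0.0345 with an estimated correlation), with the chemokine Ccl4 at least 5.81-fold higher (adjusted p = 0.00668) and Socs3, an inhibitor of cytokine signalling, 3.01-fold higher (adjusted p = 0.00273). Of the 20 glucocorticoid-responsive genes 10 rose (16 over the list alone; median 0.58, adjusted p = 3.78e-18, and 0.00122 with an estimated correlation). Mt1 (2.22-fold), Cdkn1a (1.71-fold) and Ddit4 (1.47-fold) were higher, with adjusted p of 0.00139 to 0.00408; they encode a metallothionein, a cell cycle inhibitor induced by p53 and an inhibitor of mTOR signalling. Of the 18 targets of the hypoxia-inducible factor 3 rose and 0 fell (7 and 2 over the list alone; median 0.21, adjusted p = 3.56e-05, and 0.000417 with an estimated correlation), and Slc2a1, the glucose transporter of the blood-brain barrier, was 1.99-fold higher. Of the 18 heat shock genes 2 rose (3 over the list alone; median 0.21, adjusted p = 1.4e-05, and 0.0248 with an estimated correlation), among them the co-chaperone Bag3 (2.25-fold). Of the 17 genes of the unfolded protein and integrated stress response 3 rose (6 over the list alone; median 0.25, adjusted p = 7.8e-06, and 0.0345 with an estimated correlation), among them Atf3 (at least 1.52-fold). None of the 14 glycolysis genes passed over all genes and 6 rose over the list alone (median 0.22, adjusted p = 1.03e-06, and 0.0409 with an estimated correlation). Of the 24 microglial genes 2 rose (6 over the list alone; median 0.40, adjusted p = 5.27e-08, and 0.126 with an estimated correlation). Kalrn and Unc5c, regulators of dendritic spines and of axon guidance, fell (-0.71 ± 0.16 and -0.67 ± 0.14 log2, adjusted p = 0.00697 and 0.00345).

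With the BeadChip as a block, 482 genes passed, with a log2 difference of 4.50 for Fos and a median of 1.04 for the cytokine list. Within the 2 BeadChips that held both groups, Fos was higher by 4.39 to 4.45 and the immediate early and cytokine lists by medians of 0.78 to 1.21 and 0.79 to 1.45. All 14 genes given here passed with that block. Their log2 differences moved by at most 0.76 and the list medians by at most 0.25. All 14 genes and 8 lists kept their sign in each such BeadChip. Without sham replicates 1, 2 or 3 the counts were 82, 88 and 155 genes, and without HI replicate 4 it was 81, where Ccl4 did not pass (at least 3.69-fold, adjusted p = 0.0677). This array, whose label is open to doubt (see the end), stood apart. Its mean differences from sham were 1.65 for the cytokine, 0.65 for the heat shock and 0.47 for the unfolded protein list, against 0.67 to 0.84, 0.24 to 0.31 and 0.24 to 0.26 in the other 3. Without it the medians were 0.62, 0.11 and 0.23, and all 3 lists passed.

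**Figure D1:**
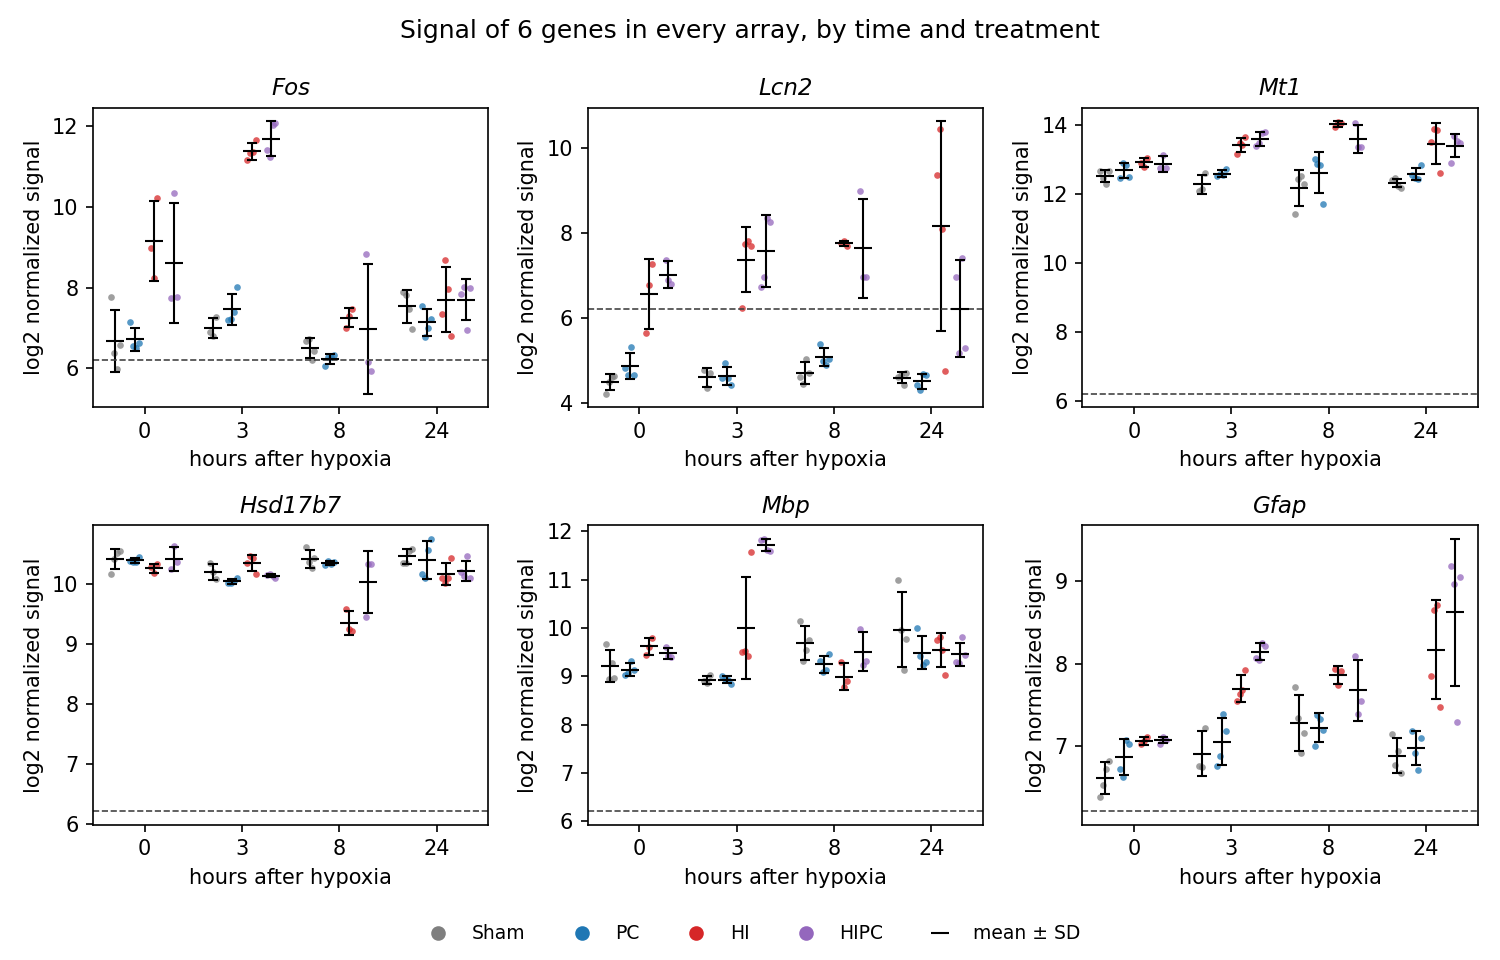
Log2 normalized signal of 6 genes (vertical axes) in every array, by hours after the hypoxia (horizontal axes) and treatment; bars are group means with SD over 3 or 4 arrays, and the dashed line is the background threshold of 6.215. Fos averaged 11.38 in HI and 7 in sham at 3 h, and Gfap was 2.44-fold higher in HI than in sham at 24 h.

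At 8 h, Mt1 and Mt2, the zinc-binding metallothioneins, were 3.61-fold higher (log2 difference 1.85 ± 0.24 SE, adjusted p = 1.57e-06) and at least 1.78-fold higher (adjusted p = 1.57e-06). Lcn2, the iron-scavenging protein lipocalin 2, was at least 2.94-fold higher (adjusted p = 0.00135). Hsd17b7, an enzyme of cholesterol synthesis, fell (-1.07 ± 0.14 log2, adjusted p = 1.57e-06), from 10.43 ± 0.15 (SD, n = 4) in sham to 9.36 ± 0.20 (SD, n = 3) in HI. In all, 421 of the 9458 genes passed limma's test, 203 higher and 218 lower. Of the 16 cholesterol synthesis genes 9 fell and 0 rose (13 fell over the list alone; median -0.56, adjusted p = 6.98e-14, and 0.00854 with an estimated correlation), Mvd (-1.10 ± 0.18) and Msmo1 (-0.98 ± 0.16) among them in log2 units. Stard4, a carrier of cholesterol within cells, also fell (-1.19 ± 0.18 log2, adjusted p = 2.93e-05). Of the 17 reactive astrocyte genes 8 rose (10 over the list alone; median 0.63, adjusted p = 3.65e-09, and 0.0536 with an estimated correlation), among them Serpina3n (2.84-fold), Emp1 (3.28-fold), Timp1 (3.08-fold) and Gbp2 (2.5-fold), with adjusted p of 6.21e-05 to 0.00792 and sham signal of Timp1 above background on 3 of 4 arrays. Of the 22 apoptosis and p53 target genes 5 rose and 1 fell (7 and 1 over the list alone; median 0.23, adjusted p = 0.000107, and 0.0536 with an estimated correlation), among them Cdkn1a (1.66-fold) and Phlda3 (1.8-fold). Of the 20 glucocorticoid-responsive genes 5 rose (7 over the list alone; median 0.26, adjusted p = 6.67e-07, and 0.089 with an estimated correlation). The endothelial surface protein gene Ly6a was 2.75-fold higher (adjusted p = 3.2e-05). P2ry13, a purine receptor of microglia, and Grm7, a presynaptic glutamate receptor, fell (-1.11 ± 0.18 and -0.83 ± 0.15 log2, adjusted p = 5.74e-05 and 0.000221). A block for the BeadChip gave 642 genes, the log2 difference of Mt1 was 1.94 and the median of the cholesterol genes -0.55. Within the 3 BeadChips that held both groups, Mt1 was higher by 1.56 to 2.51 log2 units and the cholesterol genes lay at medians of -0.55 to -0.51. In the blocked fit all 16 genes given here passed, and their log2 differences moved by at most 0.09 and the list medians by at most 0.05. In each such BeadChip all 16 genes and 4 lists kept their sign. The count was 261 without sham replicate 1, and 180 and 155 without HI replicates 2 and 3.

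At 24 h, Ccl12, a chemokine that attracts monocytes, was at least 3.8-fold higher (adjusted p = 1.3e-06), with sham signal above background on 1 of 4 arrays. Lcn2 was at least 3.88-fold higher (adjusted p = 7.39e-05), above background on 3 of 4 HI arrays (at least 2.29-fold without HI replicate 2 and 8.53-fold without replicate 4). Gfap, the intermediate filament of astrocytes, was 2.44-fold higher (log2 difference 1.29 ± 0.24 SE, adjusted p = 0.000342), at 8.17 ± 0.60 against 6.88 ± 0.21 on the log2 scale (SD, n = 4 each). In all, 958 of the 9458 genes passed limma's test, 360 higher and 598 lower. Of the 24 microglia and macrophage genes 11 rose and 2 fell (15 and 3 over the list alone; median 0.52, adjusted p = 8.95e-07, and 0.369 with an estimated correlation), with Ly86 (2.11-fold) and Fcgr3 (1.99-fold) higher. Of the 16 cytokine, chemokine and endothelial activation genes 7 rose (11 over the list alone; median 0.88, adjusted p = 1.07e-08, and 0.19 with an estimated correlation). Of the 17 reactive astrocyte genes 5 rose (6 over the list alone; median 0.37, adjusted p = 8.95e-07, and 0.19 with an estimated correlation), with Serpina3n 2.69-fold and Timp1 at least 2.26-fold higher, Timp1 above background on 1 of 4 sham arrays. Of the 5 neutrophil genes tested (of 17 fixed) 3 rose (3 over the list alone, median 1.54, adjusted p = 0.000704, and 0.188 with an estimated correlation), with S100a8 at least 3.74-fold higher (sham above background on 2 of 4 arrays) and S100a9 at least 1.42-fold (HI above background on 3 of 4). HI replicate 4 stood apart, with a mean difference of the neutrophil genes from sham of 0.16 against 1.64 to 2.13 in the other 3, and without it S100a8 was at least 5.66-fold higher. Ms4a6d, a membrane protein of macrophages, was at least 2.93-fold higher (adjusted p = 1.87e-05). Ache, the enzyme that breaks down acetylcholine, and Bdnf, a neurotrophin, fell (-0.74 ± 0.11 and -0.73 ± 0.14 log2, adjusted p = 1.87e-05 and 0.000616), as did the kinase Stk32c (-0.86 ± 0.15) and Dgat2, an enzyme of triglyceride synthesis (-0.72 ± 0.12). Of the 14 striatal neuron genes, which would mark tissue below the cortex, 2 fell (4 over the list alone; median -0.45, adjusted p = 0.0023, and 0.57 with an estimated correlation). Under median scaling 206 genes were higher and 375 lower, and in the authors' ratios 293 and 222. With the BeadChip as a block, 1274 genes passed, the log2 difference of Gfap was 1.32 and the median of the microglial genes 0.54. Within the 2 BeadChips that held both groups, Gfap was higher by 1.28 to 1.48 and the microglial and neutrophil genes by medians of 0.34 to 0.76 and 1.16 to 1.81. With that block all 14 genes given here passed. Their log2 differences moved by at most 0.13 and the list medians by at most 0.10. All 14 genes and 10 of the 12 lists kept their sign in each such BeadChip. The count was 567 without sham replicate 4 and 539, 613 and 508 without HI replicates 1, 2 and 3, and the call of the striatal genes ended without sham replicate 2 (median -0.22, adjusted p = 0.169) or HI replicate 3 (-0.31, 0.0506). The reactive astrocyte median was 0.22 without HI replicate 2.

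At 24 h the sham arrays differed from the preconditioned arrays in 971 genes and from the HI arrays in 958, so the HI arrays were also set against the PC arrays of 24 h, a comparison added after the data were seen. There 154 genes passed (121 higher, 33 lower), 88 of which had also passed against sham. Lcn2 (at least 3.88-fold), Ccl12 (at least 3.8-fold), Ms4a6d (at least 2.93-fold), Gfap (1.19 ± 0.24 log2), Serpina3n (1.69 ± 0.33) and Ly86 (1.20 ± 0.17) were higher in HI than in PC, with adjusted p of 1.02e-07 to 0.00174. Stk32c was lower (-0.81 ± 0.15, adjusted p = 0.000886). Ache (-0.12 ± 0.11, adjusted p = 0.752), Bdnf (-0.10 ± 0.14, 0.871) and Dgat2 (-0.17 ± 0.12, 0.621) did not pass. The neutrophil, reactive astrocyte and cytokine lists lay higher (medians 1.76, 0.44 and 0.94; adjusted p = 0.00615, 0.013 and 0.024 with an estimated correlation), as did hypoxia-inducible factor targets (0.10, 0.0234), and cholesterol synthesis lay lower (-0.32, 0.0179). The microglial list did not pass with an estimated correlation (median 0.47, adjusted p = 0.0819). Across genes, which are not independent replicates, the HI and PC differences from sham at 24 h correlated with r = 0.63, where unchanged groups against shared controls gave 0.5 in simulation and separate sets of sham arrays gave 0.11 to 0.42. Their covariance was 0.0333 against a simulated 0.0105. Of the called genes 141 were higher and 256 lower in both comparisons, which share their sham arrays.

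The next question was what preconditioning alone changed against sham. At 0 h, Depp1 was at least 2.9-fold higher (adjusted p = 5.29e-08) in PC (n = 4 each) and was the single gene of 9458 that passed (117 had an unadjusted p under 0.05). It was higher within each of the 4 BeadChips, and passed with the BeadChip as a block. At 3 and 8 h 0 genes passed limma's test, and 316 and 686 had an unadjusted p under 0.05. At 0 h none of the 18 hypoxia-inducible factor targets passed over all genes and 3 rose over the list alone (median 0.10, adjusted p = 2.8e-05, and 0.000232 with an estimated correlation), while Slc2a1, which belongs to that list, differed by 0.18 log2 units. None of the 15 genes of meninges and fibroblasts passed at 0 or 3 h, and 0 and 7 rose over the list alone. Their median log2 difference was 0.26 at 0 h (adjusted p = 1.07e-10, and 0.0207 with an estimated correlation) and 0.28 at 3 h (adjusted p = 1.8e-11, and 0.0291 with an estimated correlation). Within the BeadChips these medians were 0.16 to 0.35 at 0 h and 0.24 to 0.33 at 3 h, and with the BeadChip as a block 0.26 and 0.33. The 10 choroid plexus genes also lay higher at 3 h (median 0.21, adjusted p = 0.0124, and 0.535 with an estimated correlation), and at 0 h their median was -0.08 (adjusted p = 0.897). At 8 h no list passed with an estimated correlation. Without sham replicate 1 of 0 h the hypoxia and meningeal medians were 0.05 and 0.15, and without PC replicate 4 that of hypoxia was 0.06. With the BeadChip as a block 4, 0 and 0 genes passed at 0, 3 and 8 h. The count at 0 h was 2 without sham replicate 1, 2 without sham replicate 2 and 2 without PC replicate 1, and at 8 h it was 7 without PC replicate 1.

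At 24 h, Stmn4, a regulator of microtubules, was 2.05-fold higher (log2 difference 1.04 ± 0.13 SE, adjusted p = 4.04e-07) in PC than in sham, at 11.93 ± 0.19 against 10.90 ± 0.24 on the log2 scale (SD, n = 4 each). The RNA helicase Ddx5 was 1.76-fold higher (log2 difference 0.81 ± 0.17 SE, adjusted p = 0.00166). Tspoap1, a presynaptic scaffold protein, fell (-0.84 ± 0.11 log2, adjusted p = 8.88e-07). In all, 971 of the 9458 genes passed limma's test, 414 higher and 557 lower. Lgi3, Kalrn, Celsr2 and Bdnf also fell (log2 differences -0.76 ± 0.17, -0.66 ± 0.15, -0.67 ± 0.16 and -0.63 ± 0.14; adjusted p of 0.00246 to 0.00548), while the synapse and excitatory neuron lists did not pass (medians 0.06 and 0.11, adjusted p = 0.647 and 0.436). Of the 16 cholesterol synthesis genes 3 rose and 0 fell (5 and 1 over the list alone; median 0.22, adjusted p = 0.00282, and 0.873 with an estimated correlation), with Fdps (1.49-fold) and Acat2 (1.44-fold) higher. Of the 16 oligodendrocyte genes 3 fell (8 over the list alone; median -0.44, adjusted p = 0.00282, and 0.873 with an estimated correlation), among them Gpr17, a receptor of oligodendrocyte precursors (-0.65 ± 0.16 log2). Of the 19 ribosomal protein genes 2 rose (2 over the list alone; median 0.14, adjusted p = 0.0416, and 0.873 with an estimated correlation), and their median was -0.01 under median scaling. Under median scaling 201 genes were higher and 649 lower. A block for the BeadChip gave 1307 genes, the log2 difference of Stmn4 was 1.08 and the medians of the cholesterol and oligodendrocyte genes were 0.21 and -0.30. In that fit the oligodendrocyte and ribosomal lists did not pass (adjusted p = 0.064 and 0.0923). Within the 2 BeadChips that held both groups, Stmn4 was higher by 0.97 to 1.27 and these medians were 0.11 to 0.32 and -0.28 to -0.25. All 10 genes given here passed with that block, and their log2 differences moved by at most 0.09 and the list medians by at most 0.14. Within every BeadChip that held both groups, 10 of the 10 genes and 3 of the 3 lists kept their sign. The count was 534 without PC replicate 2 and 560 without PC replicate 4, where the cholesterol median was 0.12. Without sham replicate 1 the oligodendrocyte and ribosomal lists did not pass (medians -0.29 and 0.08, adjusted p = 0.0916 and 0.0916). Nor did the ribosomal list without sham replicate 2 (0.08, 0.0705) or PC replicate 1 (0.13, 0.103), and its median was 0.09 without PC replicate 3.

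**Figure D2:**
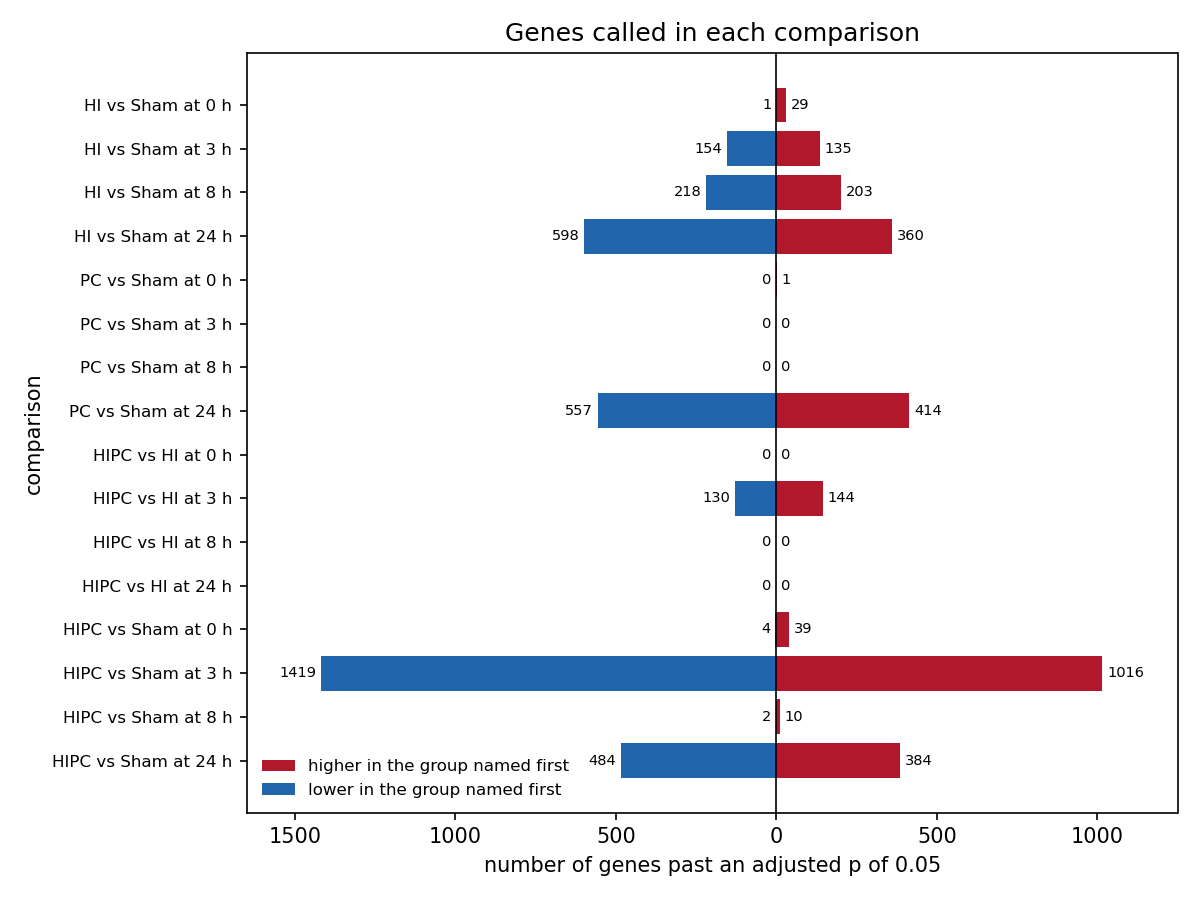
Genes past an adjusted p of 0.05 in each comparison of 2 treatments (horizontal axis, number of genes; rows, comparison and hours after the hypoxia), with higher genes to the right of 0 and lower genes to the left. The comparison of HIPC with sham at 3 h had 2435 such genes, and that of PC with sham had 1, 0, 0 and 971 at 0, 3, 8 and 24 h.

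The third question was whether preconditioning changed the response to hypoxic ischemia, as the difference between HIPC and HI. At 3 h, Mag, a myelin protein at the contact with the axon, was 3.38-fold higher (log2 difference 1.76 ± 0.32 SE, adjusted p = 0.00156) in HIPC than in HI, at 9.34 ± 0.04 in HIPC and 7.58 ± 1.16 in HI on the log2 scale (SD, n = 4 each). Mbp, myelin basic protein, was 3.28-fold higher (log2 difference 1.71 ± 0.28 SE, adjusted p = 0.000391), with 2 of its 3 probes higher. At that time 274 of the 9458 genes passed limma's test, 144 higher and 130 lower, while 0 genes passed it at 0, 8 and 24 h, where 181, 466 and 562 had an unadjusted p under 0.05. Of the 16 oligodendrocyte genes 11 rose and 0 fell (11 rose over the list alone; median 0.66, adjusted p = 2.77e-13, and 0.0385 with an estimated correlation). The neuronal activity genes Arc and Nptx2 were 1.94-fold and 1.79-fold higher (adjusted p = 0.00278 and 0.0039). Dcx, a microtubule protein of young migrating neurons, fell (-0.80 ± 0.15 log2, adjusted p = 0.00275), as did Gng2 (-0.72 ± 0.15) and Pafah1b3 (-0.65 ± 0.13). Of the 17 astrocyte identity genes 4 rose (7 over the list alone; median 0.31, adjusted p = 4.69e-06, and 0.0633 with an estimated correlation), and of the 24 microglial genes 4 did (7 over the list alone; median 0.37, adjusted p = 4.49e-09, and 0.27 with an estimated correlation). Acsbg1, an acyl-CoA synthetase of astrocytes, was 1.55-fold higher (adjusted p = 0.00275). Among the HI arrays replicate 4 stood apart, with a Mag value of 9.32 against 6.90 to 7.08 in the other 3 and 9.31 to 9.40 in HIPC, and a mean difference of the oligodendrocyte genes from sham of 1.10 against 0.04 to 0.17 and 1.01 to 1.14. Under median scaling 162 genes were higher and 27 lower, and in the authors' ratios 207 and 34. A block for the BeadChip gave 113 genes, 7 oligodendrocyte genes among them, and the log2 difference of Mag was 1.56. Within the 3 BeadChips that held both groups, that of Mag was -0.01 to 2.5 and the median of the oligodendrocyte genes -0.08 to 0.91. In the blocked fit all 8 genes given here passed. Their log2 differences moved by at most 0.20 and the list medians by at most 0.09. Within each such BeadChip 6 of the 8 genes and 2 of the 3 lists kept their sign. Without HI replicates 1, 2, 3 or 4 the counts were 55, 46, 35 and 708. Without HIPC replicates 1 or 2 they were 92 and 101.

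**Figure D3:**
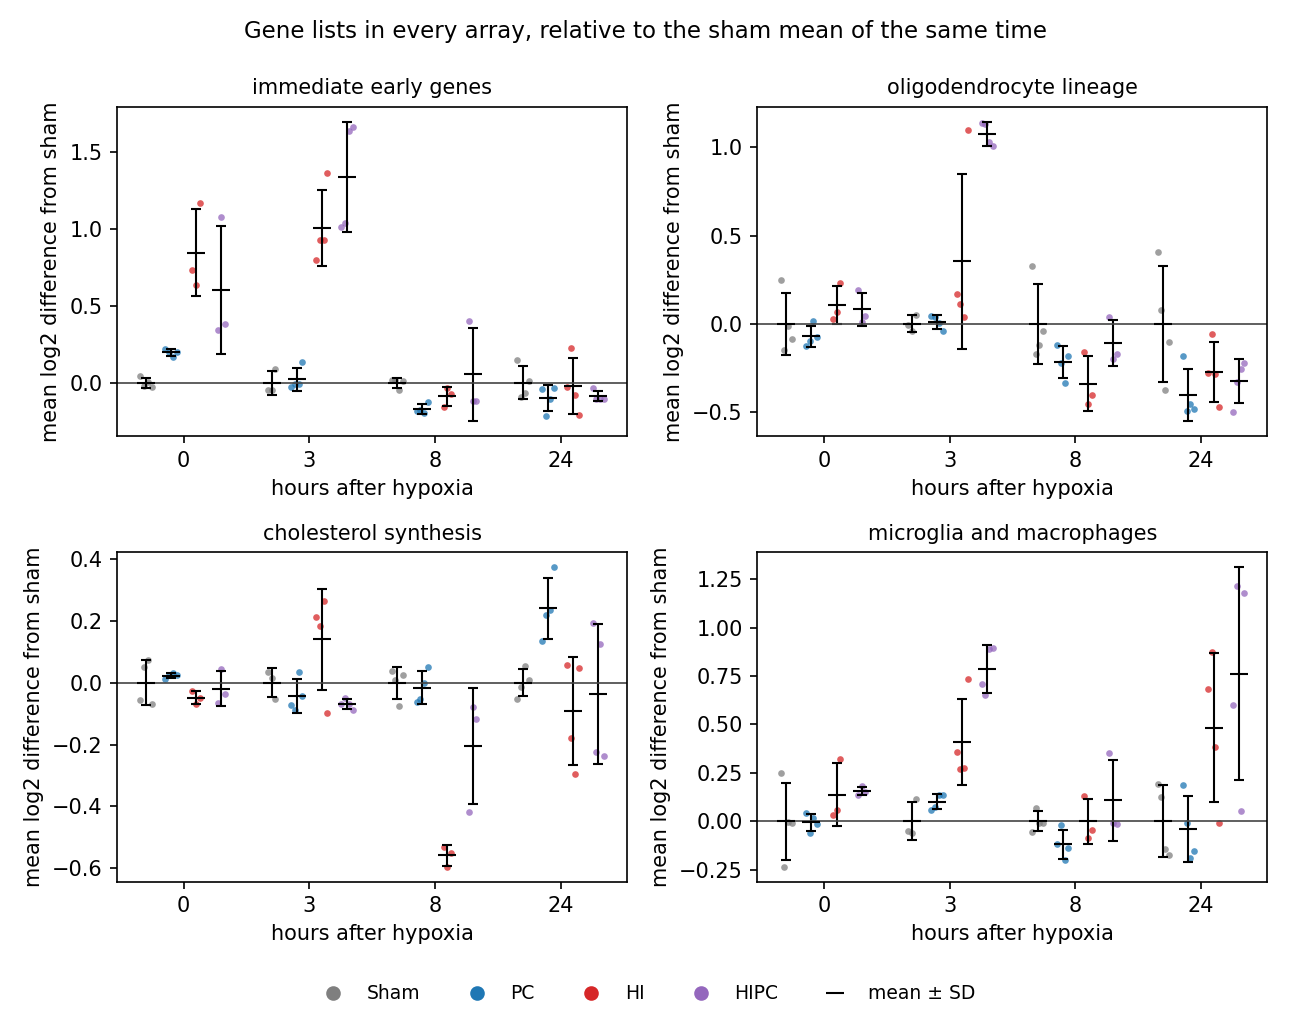
Mean over the members of 4 gene lists of the log2 value minus that of the sham arrays of the same time (vertical axes) in every array, by hours after the hypoxia (horizontal axes) and treatment; bars are group means with SD over 3 or 4 arrays. At 3 h the median log2 difference of the oligodendrocyte genes between HIPC and HI was 0.66, and at 8 h that of the cholesterol synthesis genes between HI and sham was -0.56.

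At 8 h none of the 16 cholesterol synthesis genes passed over all genes, and 6 were higher in HIPC than in HI over the list alone (median 0.31, adjusted p = 1.76e-12, and 0.0158 with an estimated correlation). The median was 0.31 with the BeadChip as a block and 0.11 to 0.48 within the 3 BeadChips (n = 3 each). HIPC replicate 1 stood apart, with a mean difference of these genes from sham of -0.42 against -0.12 to -0.08 in the other HIPC arrays and -0.60 to -0.53 in HI, and the median was 0.47 without it. The meningeal, oligodendrocyte and astrocyte identity lists also lay higher (medians 0.31, 0.19 and 0.12; adjusted p = 3.86e-06, 0.00518 and 0.00295, and 0.217, 0.582 and 0.344 with an estimated correlation). The last 2 did not pass without HIPC replicate 1 (0.192 and 0.17), nor the oligodendrocyte list without HI replicate 2 (0.0534). The reactive astrocyte list lay lower (-0.25, adjusted p = 0.0284, and 0.666 with an estimated correlation) but did not pass with the BeadChip as a block (adjusted p = 0.0632; -0.63 to 0.48 within BeadChips). Nor did it pass without HI replicate 2 (0.117) or HIPC replicates 2 or 3 (medians -0.08 and -0.12, adjusted p = 0.889 and 0.615), and without HIPC replicate 1 its median was -0.56. At 24 h none of the 24 microglial genes passed over all genes and 5 were higher over the list alone (median 0.24, adjusted p = 2.58e-06, and 0.498 with an estimated correlation). The median was 0.05 to 0.40 within the 2 BeadChips and 0.24 with the BeadChip as a block. That call ended without HI replicate 4 (median 0.10, adjusted p = 0.219), and without HIPC replicates 2, 3 and 4 the median was 0.12, 0.42 and 0.09. At 0 h the 22 immediate early genes had a median of -0.22 (adjusted p = 5.09e-05, and 0.452 with an estimated correlation), -0.76 to 0.38 within BeadChips and -0.22 with the block, with no member past the threshold (1 lower over the list alone). It did not pass without HI replicate 3 (median 0.00, adjusted p = 0.33) or HIPC replicates 1 or 3 (-0.05 and -0.14, 0.253 and 0.212), and without HI or HIPC replicate 2 the median was -0.36 and -0.47. The 14 striatal neuron genes also lay lower (median -0.265, adjusted p = 1.66e-07, and 0.452 with an estimated correlation). With the BeadChip as a block 0, 7 and 0 genes passed at 0, 8 and 24 h. Without 1 array the counts that were 0 became at most 1 at 0 h (without HIPC replicate 2), 109 at 8 h (without HIPC replicate 1; 1 without HI replicate 1 and 1 without HIPC replicate 3) and 32 at 24 h (without HIPC replicate 3; 19 without HI replicate 4).

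The last set of comparisons set preconditioned and injured cortex against sham. At 0 h, Depp1 was at least 4.07-fold higher (adjusted p = 4.99e-10) in HIPC (n = 3) than in sham (n = 4), and Hba-a1 and Slc4a1 were 2.37-fold and at least 2.13-fold higher (adjusted p = 0.00197 and 0.00142; Slc4a1 above background on 1 of 4 sham arrays). Hes5 and Sox21, transcription factors of neural progenitors, fell (-1.15 ± 0.20 and -0.58 ± 0.12 log2, adjusted p = 0.00159 and 0.00489). In all, 43 of the 9458 genes passed limma's test, 39 higher and 4 lower. Of the 22 immediate early genes 4 rose (13 over the list alone; median 0.61, adjusted p = 1.35e-14, and 0.0137 with an estimated correlation), and of the 20 glucocorticoid-responsive genes 4 did (12 over the list alone; median 0.46, adjusted p = 3.74e-11, and 0.0194 with an estimated correlation). In the fit with the BeadChip as a block 180 genes passed and the log2 difference of Hes5 was -1.08. Within the 3 BeadChips that held both groups that of Hes5 was -1.50 to -0.42, and the immediate early genes were higher by medians of 0.38 to 1.01. With that block all 5 genes given here passed, and their log2 differences moved by at most 0.17 and the list medians by at most 0.09. In each such BeadChip all 5 genes and 2 lists kept their sign. Without HIPC replicate 2 the count was 7 and neither Hes5 nor Sox21 passed (-0.89 and -0.48 log2, adjusted p = 0.103 and 0.158), and the immediate early median was 0.33. Without sham replicate 2 the count was 25.

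At 3 h, Fos was 26-fold higher (log2 difference 4.70 ± 0.48 SE, adjusted p = 1.85e-09), Fosb at least 7.4-fold higher (adjusted p = 7.74e-14) and the chemokine Ccl4 at least 9-fold higher (adjusted p = 9.65e-05). Mbp was 6.91-fold higher (log2 difference 2.79 ± 0.30 SE, adjusted p = 1.22e-08), at 11.72 ± 0.13 (SD, n = 4) in HIPC and 8.93 ± 0.09 (SD, n = 3) in sham, and Mag 6.08-fold higher (log2 difference 2.60 ± 0.34 SE, adjusted p = 2.74e-07). Dctn1, a subunit of the motor complex dynactin, fell (-2.32 ± 0.31 log2, adjusted p = 4.6e-07), as did Dcx (-1.32 ± 0.17) and the matrix protein Ncan (-1.55 ± 0.46). In all, 2435 of the 9458 genes passed limma's test, 1016 higher and 1419 lower. Of the 22 immediate early genes 17 rose (18 over the list alone; median 1.30, adjusted p = 9.28e-18, and 0.00922 with an estimated correlation). Of the 24 microglial genes 19 rose (20 over the list alone; median 0.75, adjusted p = 4.18e-12, and 0.0478 with an estimated correlation), with Csf1r (2.24-fold) and C1qb (2.13-fold) higher. Of the 16 oligodendrocyte genes 10 rose (11 over the list alone; median 1.01, adjusted p = 1.86e-10, and 0.0306 with an estimated correlation). Of the 17 astrocyte identity genes 10 rose (10 over the list alone; median 0.51, adjusted p = 1.59e-07, and 0.0196 with an estimated correlation), with Slc1a2, the main glutamate transporter, 2.44-fold and the connexin Gjb6 3.07-fold higher. Of the 18 heat shock genes 8 rose (9 over the list alone; median 0.31, adjusted p = 4.36e-05, and 0.0306 with an estimated correlation), with Hspa1a at least 4.4-fold higher, and of the 14 glycolysis genes 11 did (11 over the list alone; median 0.36, adjusted p = 1.33e-07, and 0.0306 with an estimated correlation). Markers of blood and meninges moved too: Hba-a1 was 1.73-fold higher (adjusted p = 0.00821; 0.65 to 1.11 log2 within BeadChips), and of the 15 meningeal genes 5 rose (5 over the list alone; median 0.24, adjusted p = 0.0039, and 0.257 with an estimated correlation; 0.28 to 0.38 within BeadChips). Of the 22 cell cycle genes 9 fell (9 over the list alone; median -0.27, adjusted p = 0.0039, and 0.319 with an estimated correlation). Under median scaling 987 genes were higher and 1063 lower, and in the authors' ratios 1196 and 964. In the fit with the BeadChip as a block 3003 genes passed and the log2 difference of Mbp was 2.84. Within the 3 BeadChips that held both groups Mbp was higher by 2.57 to 2.94 and the oligodendrocyte genes by medians of 0.83 to 1.14. All 14 genes given here passed with that block. Their log2 differences moved by at most 0.34 and the list medians by at most 0.10. All 14 genes and 8 lists kept their sign in each such BeadChip. Without sham replicate 1 the count was 1623.

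At 8 h, Sult1a1, a sulfotransferase of small phenols, was 2.78-fold higher (log2 difference 1.48 ± 0.26 SE, adjusted p = 0.00206) and Mt1 2.66-fold higher (log2 difference 1.41 ± 0.24 SE, adjusted p = 0.00141) in HIPC (n = 3) than in sham (n = 4). In all, 12 of the 9458 genes passed limma's test, 10 higher and 2 lower. Of the 20 glucocorticoid-responsive genes 2 rose (8 over the list alone; median 0.29, adjusted p = 5.03e-11, and 0.0407 with an estimated correlation), within BeadChips at medians of 0.06 to 0.61 and with the block at 0.29. Under median scaling and in the authors' ratios 6 genes were higher and 0 lower, and with the BeadChip as a block 82 passed, where Sult1a1 differed by 1.47 (1.19 to 1.68 within the 3 BeadChips). Without 1 array the count was 3, 43 and 66 (HIPC replicates 1, 2 and 3) or 4, 6 and 7 (sham replicates 1, 2 and 3), and without HIPC replicate 1 Mt1 did not pass (1.18 log2, adjusted p = 0.0851) and the glucocorticoid median was 0.04. At 24 h, Spp1, the secreted protein osteopontin, was 7.45-fold higher (log2 difference 2.90 ± 0.57 SE, adjusted p = 0.000976), Gfap 3.33-fold higher (log2 difference 1.74 ± 0.24 SE, adjusted p = 9.54e-06) and Cd68, a lysosomal protein of phagocytes, 2.47-fold higher (log2 difference 1.30 ± 0.23 SE, adjusted p = 0.000302). Spp1 averaged 10.32 ± 2.45 in HIPC and 7.43 ± 0.43 in sham on the log2 scale (SD, n = 4 each); without HIPC replicate 3 (6.75, against 10.70 to 12.09 in the others) it was 17-fold higher, and without replicate 2 4.96-fold. In all, 868 of the 9458 genes passed limma's test, 384 higher and 484 lower. Of the 24 microglia and macrophage genes 13 rose and 0 fell (16 and 1 over the list alone; median 0.74, adjusted p = 9.44e-16, and 0.149 with an estimated correlation), with Lyz2 (2.86-fold), Ly86 (2.22-fold) and C1qb (2.14-fold) higher (adjusted p of 3.57e-05 to 7.29e-05). Of the 10 choroid plexus genes 3 fell (4 over the list alone; median -0.43, adjusted p = 0.00125, and 0.288 with an estimated correlation), among them the growth factor Igf2 and the secreted antagonist Sostdc1 (-0.58 ± 0.13 and -0.81 ± 0.19 log2). Under median scaling 351 genes were higher and 144 lower, and in the authors' ratios 557 and 91. In the fit with the BeadChip as a block 1060 genes passed and the log2 difference of Gfap was 1.77. Within the 2 BeadChips that held both groups Gfap was higher by 1.36 to 2.30 and the microglial and choroid plexus medians were 0.71 to 0.76 and -0.46 to -0.43. In the blocked fit all 8 genes given here passed, and their log2 differences moved by at most 0.23 and the list medians by at most 0.07. Within every BeadChip that held both groups, 8 of the 8 genes and 2 of the 2 lists kept their sign. Against the PC arrays 108 genes passed (100 higher, 8 lower, 76 also called against sham), with the microglial list higher (median 0.72, adjusted p = 0.00691 with an estimated correlation) and Sostdc1 not passing (-0.23 ± 0.19 log2, adjusted p = 0.77). Without sham replicate 4 the count against sham was 507.

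Whether the difference between HI and sham itself changed with time was tested between successive times. From 3 to 8 h, 231 of the 9458 genes passed limma's test, 125 higher and 106 lower. The HI effect on Fos fell by 3.64 ± 0.68 log2 units (adjusted p = 0.00244), and that on Egr1, another immediate early transcription factor, by 1.49 ± 0.34 (adjusted p = 0.013). Of the 22 immediate early genes 9 fell in their HI effect (16 over the list alone; median -0.90, adjusted p = 4.35e-20, and 0.00427 with an estimated correlation). Of the 16 cholesterol synthesis genes 6 did (10 over the list alone; median -0.67, adjusted p = 1.29e-13, and 0.00547 with an estimated correlation), and Stard4 and Insig1, which bind sterols or sense them, changed by -1.54 ± 0.25 and -1.32 ± 0.28 log2 units (adjusted p = 0.000616 and 0.00828). Lrrtm1, a synaptic adhesion protein, rose in its HI effect (1.13 ± 0.25 log2, adjusted p = 0.0102). From 8 to 24 h, 341 of the 9458 genes passed limma's test, 107 higher and 234 lower. The HI effect on Lrrtm1, Nptx2 and Phlda3 fell (log2 differences -1.58 ± 0.24, -1.57 ± 0.25 and -1.14 ± 0.21; adjusted p of 0.000223 to 0.00116), and that on Stard4 rose (1.16 ± 0.25 log2, adjusted p = 0.00473). Of the cholesterol synthesis genes 4 rose in their HI effect (6 over the list alone; median 0.41, adjusted p = 9.47e-06, and 0.414 with an estimated correlation). From 0 to 3 h 0 genes passed limma's test (490 had an unadjusted p under 0.05). Under median scaling 46 genes were higher and 46 lower from 3 to 8 h (37 and 50 in the authors' ratios), and 30 and 54 from 8 to 24 h (42 and 35). In the fit with the BeadChip as a block 0, 338 and 559 genes passed from 0 to 3, 3 to 8 and 8 to 24 h, Fos changed by -3.72 and the cholesterol genes by medians of -0.55 and 0.42. From 3 to 8 h the count was 103, 109 and 136 without sham replicates 1, 2 and 3 of 3 h, 105 without HI replicate 4 of 3 h, and 92 and 86 without HI replicates 2 and 3 of 8 h. From 8 to 24 h it was 207, 165 and 185 without the HI replicates of 8 h, 206 without sham replicate 4 and 190 without HI replicate 1 of 24 h, and from 0 to 3 h 2 without HI replicate 3 of 0 h and 1 without HI replicate 4 of 3 h.

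The lists not yet named are given for HI against sham at 24 h, the time with the most called genes in that comparison, with adjusted p from an estimated correlation. Of the 16 oxidative stress and metallothionein genes 2 rose and 0 fell (2 and 0 over the list alone; median 0.11, adjusted p = 0.533). Of the 15 interferon response genes 1 rose and 0 fell (1 and 0 over the list alone; median 0.08, adjusted p = 0.57). Of the 18 excitatory neuron genes 1 rose and 0 fell (1 and 0 over the list alone; median 0.07, adjusted p = 0.826). Of the 14 inhibitory neuron genes 0 rose and 1 fell (0 and 1 over the list alone; median -0.07, adjusted p = 0.951). Of the 21 synapse genes 1 rose and 1 fell (1 and 4 over the list alone; median 0.00, adjusted p = 0.951). Of the 16 genes of endothelial cells and pericytes 2 rose and 1 fell (2 and 1 over the list alone; median 0.05, adjusted p = 0.725). Of the 25 genes of the mitochondrial respiratory chain 0 rose and 0 fell (0 and 0 over the list alone; median 0.06, adjusted p = 0.656). With the preset correlation the interferon list passed (adjusted p = 0.0349), but not without sham replicate 3 (0.107) or HI replicates 2 or 3 (0.0988 and 0.157), nor with the BeadChip as a block (0.0961), and its median was 0.14, 0.17 and 0.13 without sham replicate 4 and HI replicates 1 and 4. The endothelial list, which did not pass, did so without HI replicate 1 (median 0.09, adjusted p = 0.0157) and against the PC arrays (0.00934, but 0.393 with an estimated correlation), and the oxidative stress list did so without HI replicate 4 (0.0257). The list of erythroid genes kept 4 members and was not tested as a list.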

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

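The tests on HI replicate 4 of 3 h, on the maturation and blood cell gene lists and on the 24 h sham arrays, and the second set of draws of the times, were chosen only after the patterns they test were seen, while the splits of the arrays were set before their results were seen. A gap test for single arrays was run in groups of 4: it marked 12 of the 131 groups of gene values, 8 of the 64 of gene lists and 1 of the 11 of array signal, and chance alone marks about 1 in 20 groups.

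HI replicate 4 of 3 h lay far from the other 3 HI arrays in 6 of these genes. On the log2 scale its value was the highest for Mag (9.32), Mbp (11.58), Arc (8.09), Atf3 (7.76) and Ccl4 (10.72), and the lowest for Pafah1b3 (10.12). Its mean difference from sham was also the highest for the oligodendrocyte (1.1), cytokine (1.65), heat shock (0.65) and unfolded protein (0.47) lists, while HI replicate 1 was the lowest for hypoxia-inducible factor targets (0.27).

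Other arrays far from their group were these. At 24 h, HIPC replicate 3 was lowest for C1qb (9.11) and Gfap (7.29), HIPC replicate 1 was highest for Igf2 (12.5) and lowest for the choroid plexus list (-0.67), and HI replicate 4 was lowest for S100a8 (6.32) and S100a9 (5.51). Sham replicate 2 was highest for Cd68 (6.96), HI replicate 1 lowest for the endothelial list (-0.2) and PC replicate 1 highest for the oligodendrocyte list (-0.18). PC replicate 3 of 8 h had the highest mean signal of its group (317.0).

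The HI effect differed between successive times by limma's test of the difference. From 3 to 8 h, 231 genes passed, with log2 differences of -3.64 for Fos, -1.49 for Egr1, -1.54 for Stard4, -1.32 for Insig1 and 1.13 for Lrrtm1, and medians of -0.67 for cholesterol synthesis and -0.90 for immediate early genes. From 8 to 24 h, 341 genes passed, with -1.58 for Lrrtm1, -1.57 for Nptx2, -1.14 for Phlda3 and 1.16 for Stard4, and a median of 0.41 for cholesterol synthesis (adjusted p = 0.414 with an estimated correlation). Draws of the times within each treatment called up to 5732, 4885 and 6141 genes from 0 to 3, 3 to 8 and 8 to 24 h, where the real counts were 0, 231 and 341. As many as the real count came from 100, 11 and 19 of 100 draws, the real one included. Counts this far above the real ones point to a structure of the samples: these draws also mix the whole difference between the times, so they decide nothing about chance. In a second set the mean difference between the 2 times was first taken out of each gene, and the highest other counts were 136, 21 and 70. By this set chance is unlikely for 3 to 8 and 8 to 24 h: 1 of 100, the real one, called as many. From 0 to 3 h all 100 do, because the real count is 0, which decides nothing. The times lie on different BeadChips; with the BeadChip as a block 338 and 559 genes passed from 3 to 8 h and 8 to 24 h.

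Oligodendrocyte genes were higher in HIPC than in sham and HI at 3 h. More white matter would dilute neuron genes. In HIPC against sham the mature median was 0.234 (0.099 to 0.437 over members) and the immature -0.274, so white matter stays open. More mature cortex in the HIPC pups predicts mature above immature neuron genes, and the difference of their medians was 0.509 (0.343 to 0.753); this stays open, as a hypothesis found on the same arrays, and these lists also moved in other comparisons. For HIPC against HI, a wrong label of HI replicate 4 predicts that this array follows the HIPC difference over all genes: its slope was 0.71, against 0.60 to 0.68 for the HIPC arrays and -0.10 to 0.18 for the other HI arrays, so a wrong label stays open, and so does an HI pup with a response like that of HIPC, which was not tested. The correlation with the trend of overall signal was 0.33, which decides nothing.

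At 24 h PC against sham called 971 genes and HI against sham 958. Overall signal would make the difference follow the within-group trend on signal, and the correlation was -0.08, which argues against it. Sham arrays standing apart from all others predict few calls without them, and HI against PC called 154 genes against 958 for HI against sham, so this stays open. With 1 array left out the lowest count was 534 of 971, between the bounds set for a single deviating array. An effect of preconditioning on the cortex at 24 h stays open too, and was not tested apart from the sham arrays.

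Red cell and neutrophil genes were higher in HI than in sham at 0 h. More blood left in the tissue predicts that other blood cell genes rise with them, and the median of 16 such genes was 0.127 (0.098 to 0.247 over members), below the bound of 0.2 set for it and above 0. More blood and a change in the circulating cells therefore cannot be told apart, because the median fell between the 2 bounds. This test replaced an earlier one on Hba-a1, Alas2 and Slc4a1, which had been picked because they rose and so could decide nothing. At 3 h these 3 genes averaged 8.66 to 9.15 in all 12 arrays of PC, HI and HIPC against 8.43 to 8.52 in sham, and blood in that tissue was not tested.

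The counts of called genes were set against all other splits of the same arrays into groups of the same sizes. Chance is excluded, with 1 of 35 splits as large, for HI against sham at 0 h (30 genes, highest other split 8), 3 h (289 and 40), 8 h (421 and 91) and 24 h (958 and 473), for PC against sham at 24 h (971 and 127), and for HIPC against sham at 3 h (2435 and 1226), 8 h (12 and 8) and 24 h (868 and 501). At 24 h the split with 473 genes parts the BeadChips, and 1274 genes passed with the BeadChip as a block. For HIPC against sham at 0 h the share lay above that bound, since 2 of 35 splits called as many (43 genes, highest other 47). The split with 47 moves sham replicate 1, which lies on BeadChip 11, to the HIPC arrays, and 180 genes passed with the BeadChip as a block.

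For HIPC against HI at 3 h the share also lay above the bound of 0.05: 2 of 35 splits called as many (274 genes, highest other 331). So did that for PC against sham at 0 h, where 13 of 35 splits called as many as the real 1 (highest other 658). They ignore the BeadChips, so they cannot decide on Depp1, which was higher within each. Where the real count is 0 all 35 splits call as many, which decides nothing. This holds for PC against sham at 3 and 8 h (highest others 0 and 190) and HIPC against HI at 24 h (406). Splits that call 658, 190 or 406 genes point to a structure of the samples. HIPC against HI at 0 and 8 h has 10 splits, too few for a share under 0.05. All called as many as the real 0 (highest others 1 and 95).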

How the results depend on the processing

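The alternatives with the BeadChip 11 arrays, the 2 brightest HIPC arrays of 3 h left out, or the sham arrays of 24 h replaced by PC arrays, were chosen after the data were seen, and all other alternatives before the data were examined. Each alternative changed 1 choice and kept the rest, except that the authors' ratios replaced background correction and normalization together. Counts below are genes past an adjusted p of 0.05 in limma's test, given where they moved by over 1.5 times, and the cause of these changes was not tested unless it is named. Signal over background limits what can be read: where the mean of a group lay below the background threshold only a lower bound of the fold is given, and quantile normalization assumes that most genes stay unchanged. For the 26 gene lists in 16 comparisons, 7623 values stayed on their side of the threshold over all alternatives, 292 no longer passed, 295 newly passed and 16 that had passed changed sign; for the 471 gene differences chosen by the naming rule these numbers were 8318, 1386, 0 and 1. Of the list values that had not passed, 567 changed sign, 11 of them newly passing. Of these 471 gene differences, 248 passed in every fit with 1 array left out, and 43 did not pass with the BeadChip as a fixed block. Wherever the median, the mean and the test of a list differed in sign, the list did not pass.

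No background correction gave HIPC against HI 1 at 8 h and the difference of HI effects 1 from 0 to 3 h, and an offset of 50 gave HIPC against HI 2 at 8 h and the difference of HI effects 1 from 0 to 3 h. Median scaling in place of quantile normalization gave HI against sham 50, 200 and 581 at 0, 8 and 24 h, HIPC against sham 82, 6 and 495 at 0, 8 and 24 h, and the difference of HI effects 92 from 3 to 8 h and 84 from 8 to 24 h. Under it the median over all genes lay further than 0.1 from 0 only in the difference of HI effects from 0 to 3 h (-0.1148), where 0 genes passed. The authors' ratios gave HI against sham 50, 202 and 515 at 0, 8 and 24 h, PC against sham 531 at 24 h, HIPC against HI 1 at 24 h, HIPC against sham 116 and 6 at 0 and 8 h, and the difference of HI effects 1 from 0 to 3 h, 87 from 3 to 8 h and 77 from 8 to 24 h. Without the filter, with more genes to adjust for, the counts were HI against sham 186 at 3 h, HIPC against HI 126 at 3 h, and the difference of HI effects 145 from 3 to 8 h, and the stricter filter gave HIPC against HI 1 at 8 h. Every probe tested, and so more tests, gave PC against sham 1479 at 24 h. With only the arrays of the times compared, fewer arrays estimate the spread, and the counts were HI against sham 706, 157 and 251 at 3, 8 and 24 h, PC against sham 9 and 354 at 3 and 24 h, HIPC against HI 510 and 1 at 3 and 8 h, HIPC against sham 24, 6 and 250 at 0, 8 and 24 h, and the difference of HI effects 1 from 0 to 3 h, 372 from 3 to 8 h and 123 from 8 to 24 h. A log2 difference of at least 1 beside the adjusted p left, by construction, HI against sham 19, 30, 33 and 31 at 0, 3, 8 and 24 h, PC against sham 2 at 24 h, HIPC against HI 6 at 3 h, HIPC against sham 14, 128, 7 and 31 at 0, 3, 8 and 24 h, and the difference of HI effects 32 from 3 to 8 h and 25 from 8 to 24 h. The number of gene lists past the threshold at 0, 3, 8 and 24 h was HI against sham 10, 17, 8 and 8, PC against sham 7, 8, 6 and 3, HIPC against HI 2, 13, 9 and 10, HIPC against sham 8, 16, 11 and 9 with the preset correlation, and HI against sham 3, 8, 1 and 0, PC against sham 2, 1, 0 and 0, HIPC against HI 0, 1, 1 and 0, HIPC against sham 3, 9, 2 and 0 with the estimated correlation.

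Array weights gave HI against sham 143, 2477, 1460 and 1487 at 0, 3, 8 and 24 h, PC against sham 5, 328, 48 and 1524 at 0, 3, 8 and 24 h, HIPC against HI 1, 2150, 920 and 49 at 0, 3, 8 and 24 h, HIPC against sham 594 and 4185 at 0 and 3 h, and the difference of HI effects 82 from 0 to 3 h, 1468 from 3 to 8 h and 997 from 8 to 24 h. The estimation of these weights, which ran from 0.13 to 4.41, stopped before it converged, and a gene-by-gene estimator gave HI against sham 119, 2367, 1439 and 1378 and PC against sham 5, 289, 33 and 1453 at 0, 3, 8 and 24 h. For PC against sham at 3 h, where the weights gave 328 genes, the highest other of 35 splits of the arrays, weighted anew, gave 268. With the BeadChip as a fixed block the counts were HI against sham 482 and 642 at 3 and 8 h, PC against sham 4 at 0 h, HIPC against HI 113 and 7 at 3 and 8 h, HIPC against sham 180 and 82 at 0 and 8 h, and the difference of HI effects 559 from 8 to 24 h. As a random block, with a consensus correlation of 0.177, it gave HI against sham 47, 484 and 703 at 0, 3 and 8 h, PC against sham 2 at 0 h, HIPC against HI 432 and 6 at 3 and 8 h, HIPC against sham 36 at 8 h, and the difference of HI effects 395 from 3 to 8 h and 577 from 8 to 24 h.

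The replicate numbers do not pair the arrays: no label says what they share, and the deviations of arrays with the same number correlated with medians of 0.01, 0.04, 0.1 and 0.23 at 0, 3, 8 and 24 h, with 6 of 19, 8 of 21, 9 of 19 and 20 of 24 pairs over 0.1. With the replicate number as a block the counts were HI against sham 46 at 0 h, PC against sham 3 at 0 h, HIPC against sham 80 at 0 h, and the difference of HI effects 4 from 0 to 3 h, and the others stayed within 1.5 times. Within groups the BeadChip took up 44.6% and the replicate number 37.6% of the variation, each with 16 levels.

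Leaving out each array in turn gave HI against sham 6 to 33 at 0 h, 81 to 275 at 3 h, 155 to 373 at 8 h, 508 to 1132 at 24 h. It gave PC against sham 1 to 2 at 0 h, 0 to 0 at 3 h, 0 to 7 at 8 h, 534 to 923 at 24 h, and HIPC against HI 0 to 1 at 0 h, 35 to 708 at 3 h, 0 to 109 at 8 h, 0 to 32 at 24 h. It also gave HIPC against sham 7 to 45 at 0 h, 1623 to 2219 at 3 h, 3 to 66 at 8 h, 507 to 928 at 24 h, and the difference of HI effects 0 to 2 from 0 to 3 h, 86 to 226 from 3 to 8 h, 165 to 366 from 8 to 24 h. Leaving out the 2 brightest HIPC arrays of 3 h gave HIPC against HI 467 at 3 h, and PC arrays in place of sham arrays gave HI against sham 154 at 24 h and HIPC against sham 108 at 24 h. Without the arrays of BeadChip 11, run for the 4 comparisons at 0 h and the difference of HI effects from 0 to 3 h, no count moved over 1.5 times.

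Values that had passed and changed sign were these, and the cause was not tested. Under median scaling the ribosomal proteins of PC against sham at 24 h had a median of -0.01. With array weights the medians were -0.026 for excitatory neurons in PC against sham at 0 h, -0.042 for the unfolded protein response in HIPC against HI at 8 h, and -0.007 for glycolysis and 0.131 for cytokines in HIPC against HI at 24 h. Without sham replicate 1 of 0 h the excitatory neuron median was -0.019 in HI and -0.054 in PC against sham, and without both arrays of BeadChip 11 -0.019 and -0.055. With 1 array left out these medians ran from -0.019 to 0.201 in HI and from -0.054 to 0.148 in PC. Without HIPC replicate 1 of 8 h the unfolded protein median was -0.056 against HI and -0.038 against sham, and with 1 array left out the highest values were 0.197 and 0.134. In HIPC against HI at 24 h the cytokine median was 0.096, 0.056 and 0.179 without HI replicate 2, HI replicate 3 and HIPC replicate 3. It ran from -0.277 to 0.179 with 1 array left out, and the cell cycle median from -0.004, without HIPC replicate 4, to 0.203. With PC arrays in place of sham arrays at 24 h, the log2 difference of Dlg4 in HI was -0.101 and the oligodendrocyte median in HIPC 0.054.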

Other observations

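At 3 h, of the 16 cytokine, chemokine and endothelial activation genes 14 rose in HIPC against sham (15 adjusted over the list alone; median log2 difference 1.14, adjusted p = 2.9e-11, and adjusted p = 0.0478 with an estimated correlation), among them the chemokine Ccl3 (at least 3.21-fold) and Cd14, a receptor for bacterial lipopolysaccharide (at least 1.72-fold). Of the 20 glucocorticoid-responsive genes 16 rose (17 adjusted over the list alone; median log2 difference 0.72, adjusted p = 4.24e-13, and adjusted p = 0.013 with an estimated correlation), with Sult1a1 2.84-fold and Dusp1 2.23-fold higher in limma's test (adjusted p = 2.27e-05 and 1.4e-05). Of the 18 hypoxia-inducible factor targets 8 rose and 4 fell (8 and 4 adjusted over the list alone; median log2 difference 0.21, adjusted p = 0.023, and adjusted p = 0.0413 with an estimated correlation), with Slc2a1 2.24-fold and the transcription factor Bhlhe40 2.04-fold higher (adjusted p = 4.59e-06 and 0.00021). The glycolytic enzymes Pfkp and Aldoc were 2.65-fold and 1.81-fold higher (adjusted p = 8.85e-05 and 4.83e-05). Within the 3 BeadChips that held both groups the cytokine, glucocorticoid and hypoxia medians were 0.67 to 1.65, 0.61 to 0.87 and 0.10 to 0.24, and with the BeadChip as a block 1.28, 0.74 and 0.21.

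In HI against sham at 3 h, Gjb6 and Ntsr2, a neurotensin receptor of astrocytes, were 1.82-fold and 1.64-fold higher (adjusted p = 0.0123 and 0.0376 in limma's test), and of the 17 astrocyte identity genes 2 rose (5 adjusted over the list alone; median log2 difference 0.24, adjusted p = 3.56e-05, and adjusted p = 0.0432 with an estimated correlation). In HIPC against sham at 0 h, Slc2a1 was 1.81-fold higher (adjusted p = 0.0072), and 1 of the 18 hypoxia-inducible factor targets rose (5 adjusted over the list alone; median log2 difference 0.12, adjusted p = 0.00189, and adjusted p = 0.00987 with an estimated correlation).

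The maturation lists, written after the HIPC arrays of 3 h were seen, held 35 genes of mature and 38 of immature neurons. In HIPC against sham at 3 h, 13 mature genes rose and 1 fell (median log2 difference 0.23, p = 0.0414 from camera with an estimated correlation), and 0 immature genes rose and 16 fell (-0.27, p = 0.0158). In HIPC against HI the medians were 0.19 and -0.15 (p = 0.0408 and 0.0513 from limma's camera with an estimated correlation). The shift was not particular to HIPC at 3 h. Against sham the mature median was 0.19 in HI and 0.19 in HIPC at 0 h (p = 0.0225 and 0.0308 from limma's camera with an estimated correlation) and -0.19 in both at 24 h (0.0954 and 0.126). The immature median was -0.14 in HI at 3 h (0.0382). These lists were first run with 5 genes that earlier output had shown (Scn4b, Snap91, Kalrn, Tnc and Celsr3), and rerun without them.

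At 8 h HIPC replicate 1 stood apart. By its mean difference from sham it was nearer to HI for cholesterol synthesis (-0.42). It went beyond HI for reactive astrocytes (1.25, HI 0.76 to 0.84, other HIPC 0.23 to 0.25). So it did on principal component 3 (-22.12, HI -12.46 to -7.45). Without this array 109 genes passed in HIPC against HI at 8 h.

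At 24 h the HI and HIPC differences from sham correlated over genes with r = 0.82 (0.33 to 0.58 with separate sham arrays, 0.5 for unchanged groups in simulation) and a covariance of 0.048 against a simulated 0.0106. They shared 196 higher and 288 lower calls. For PC and HIPC r was 0.65 (0.16 to 0.43), the covariance 0.0341 against 0.0106, and the shared calls 169 and 221. All of these comparisons share their sham arrays.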
